A study of Arabidopsis thaliana with 12 samples.

How the data were processed

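The samples were leaves of 3-week-old Arabidopsis thaliana (Columbia-0) of 2 lines, cat2-2 gox1 and cat2-2 gox2 in the sample titles and cat2 gox1 and cat2 gox2 below, each under high CO2 or after 3 h of high light in ambient air. There were 3 biological repeats for each of the 4 groups, so 12 libraries, and every library came from the pooled leaves of 15 plants. The labels describe stranded mRNA libraries. According to the submitters' processing notes, reads were trimmed with Trim Galore 0.3.3, aligned with TopHat2 2.1.0 to the TAIR10 genome, and assigned to genes with featureCounts of Subread 1.4.6. The deposited table holds raw counts of reads per gene, without normalization or filtering, and every value is a whole number of 0 or more. The strand setting of the counting and the handling of reads with several alignments are not given in the sources used here. Reads shared between similar genes may therefore have been dropped or placed on either one, which matters for GOX1 and GOX2.

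The table has 33604 entries, of which 2 name no gene, leaving 33602 loci. No library has a count at 8982 of these loci. All 279 chloroplast and mitochondrial loci are listed at 0 in all 12 libraries, so organellar transcripts were not analysed here. Gene symbols were looked up by locus code in a reference table of the TAIR10.1 assembly, which named 32835 of the loci and left 767 without a name. Coordinates are those of TAIR10.1. Total counts of replicates 1, 2 and 3 were 20330914, 22895740 and 23266458 for cat2 gox1 under high CO2, 22005002, 21454877 and 20768082 for cat2 gox1 after high light, 20335019, 22497526 and 19883772 for cat2 gox2 under high CO2, and 19571516, 20994540 and 25314811 for cat2 gox2 after high light. Levels are given as CPM, counts relative to the scaled library total, and 1 count corresponds to at most 0.0511 CPM.

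Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr at its settings of a minimum count of 10 and a minimum total of 15, given the 4 groups. This left 18967 genes with 99.96% of all counts. Libraries were scaled by the trimmed mean of M values (TMM), and CPM values below are on that scale. A negative binomial model with 1 mean per group was fitted to all 12 libraries together, because 3 libraries per group give little information on the spread. The biological coefficient of variation was 0.211. Each of 5 comparisons used edgeR's two-sided quasi-likelihood test, with p-values adjusted by Benjamini-Hochberg over the 18967 genes and a threshold of 0.05. The comparisons were high light against high CO2 within each line, cat2 gox2 against cat2 gox1 within each condition, and the difference between the lines' light responses (the interaction). Log2 fold changes are given with an approximate standard error (SE), the size of the change divided by the square root of the test's F statistic. It can be too small for genes with few counts in a group. CPM values are given as mean ± SD of 3 libraries. Where a group had no count of a gene, the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts the ratio is given with an exact 95% binomial interval. These bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

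Before the data were examined, 22 gene lists with 371 members were written from textbook knowledge. They cover photorespiration, the light-harvesting antenna, the Calvin cycle, hydrogen peroxide and mitochondrial stress markers, heat shock and chaperones, antioxidant enzymes and glutathione, jasmonate, salicylate, ethylene, abscisic acid and dehydration, flavonoids and anthocyanins, aliphatic glucosinolates, indolic glucosinolates and camalexin, senescence and chlorophyll breakdown, sugar starvation, the unfolded protein response of the endoplasmic reticulum, the circadian clock, high-light and UV markers, guard cells, phloem, dividing cells and the shoot meristem. Of the members, 357 were among the genes tested. A list needed 3 tested members, which left 21 lists, since the shoot meristem list had only KNAT6. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg within each comparison. Beside it stand camera with a correlation estimated from the data, and fry, which tests whether the members of a list move, on balance, in a common direction. Counts of changed members are given both over all genes tested and adjusted over the list alone.

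The genes named in the text follow a rule fixed before the data were examined. It takes the 3 mutated genes. For each comparison it takes the 8 largest rises and the 8 largest falls past the threshold among genes with a mean of at least 5 CPM and, between groups, no overlap of their replicates, which a gene without any difference shows with a probability of 0.1. For each list it takes up to 2 members with the largest rise and 2 with the largest fall past the threshold, or, where none passed, the 2 with the smallest unadjusted p as values only. A part of these is named, and genes from outside the rule are pointed out.

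The alternatives chosen before the data were examined were scaling by the median of ratios, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, a term for the replicate number (block), DESeq2 1.42.0, a fit of only the libraries compared, a test against a fold of 1.5, an estimated correlation or fry for the lists, and each library left out in turn. After the data were seen, the fits were also run without the high CO2 libraries of number 3, without all libraries of number 3, and without the high CO2 libraries of number 3 and the high light library of number 2 of cat2 gox2. The labels do not say that replicate numbers pair the libraries. Deviations from the group means correlated for all same-numbered libraries of cat2 gox1 and cat2 gox2 under high CO2 (0.433, 0.501 and 0.765), so the blocked result is given beside that comparison. With 3 libraries per group, an outlying number 3 in both lines by itself makes numbers 1 and 2 deviate together. Number 1 of cat2 gox1 went best with number 2 of cat2 gox2, so a pairing of numbers 1 and 2 is not shown. A replicate number holds 1 library per group, so no test within a number is possible.

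The procedure was tested on simulated counts in which 200 genes were changed, 50 at each fold. For the comparison of the lines under high light, on 18787 genes, it recovered 4% of the changed genes at a fold of 1.5, 52% at 2, 88% at 4 and 96% at 8, with 7 false calls among 127. For the comparison under high CO2, on 18837 genes, the shares were 4%, 46%, 96% and 86%. For the interaction, on 18775 genes, they were 0%, 14%, 64% and 82%.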

Results

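Messenger RNA was sequenced from leaves of 2 Arabidopsis lines that each carry a mutation in CATALASE 2 (CAT2), the main leaf catalase, and in GLYCOLATE OXIDASE 1 or 2 (GOX1, GOX2). Glycolate oxidases are peroxisomal enzymes that oxidise photorespiratory glycolate and release hydrogen peroxide, which catalase breaks down. Plants grew at 3000 ppm CO2 and 120 µmol photons per square metre per second, where photorespiration is low. High light plants then spent 3 h at 400 ppm CO2 and 1200 µmol photons per square metre per second. Light and CO2 thus changed together, and no group stayed at high CO2 for the same 3 h. Effects of light, CO2 and elapsed time cannot be told apart, so high light below stands for the whole change. The design asks how each line responds to conditions that promote photorespiration, and whether loss of GOX1 and loss of GOX2 have different effects on that response. Each line and condition had 3 libraries.

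The condition separated the libraries, and along the dimension that separated them the lines parted only after high light. In multidimensional scaling the first dimension, with 81.9% of the variance, placed all high CO2 libraries between -3.11 and -2.07 and all high light libraries between 2.01 and 3.15. The high light libraries of cat2 gox1 lay at 2.01 to 2.41 and those of cat2 gox2 at 2.83 to 3.15. Under high CO2 the number 3 libraries of both lines stood apart from numbers 1 and 2. Compared with the mean of the other libraries of their group, 501 genes were at least 2-fold higher in both number 3 libraries, 508 were at least 2-fold lower in both, and 12 went opposite ways.

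**Figure D1:**
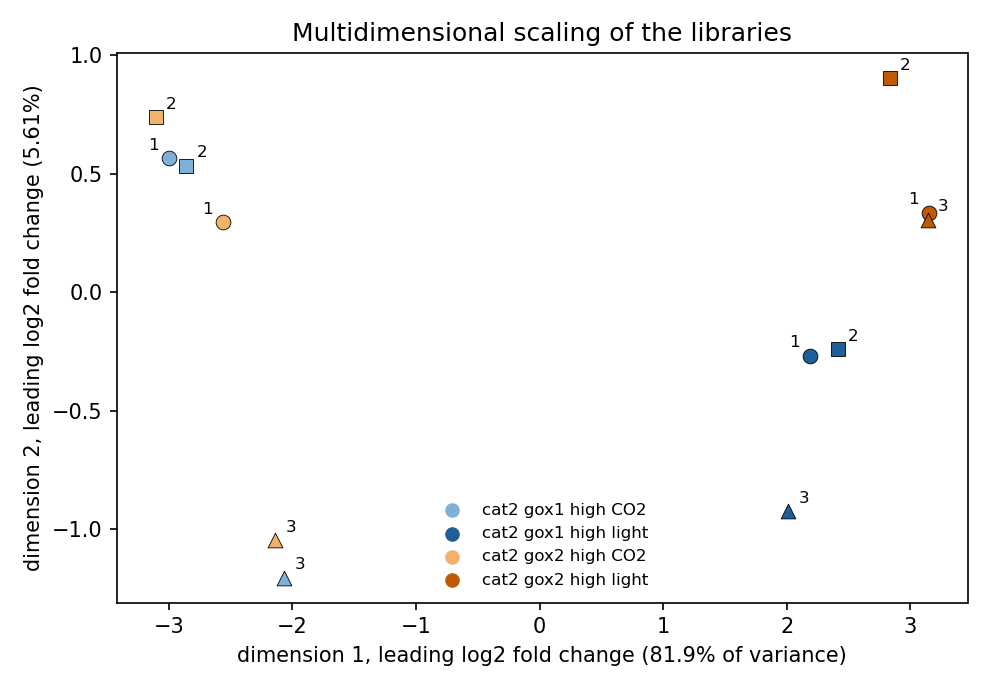
Multidimensional scaling of the 12 libraries by leading log2 fold changes, with the first dimension (81.9% of the variance) on the x axis and the next (5.61%) on the y axis. Each point is a library, coloured by group and numbered by replicate. High CO2 libraries lie on the left and high light libraries on the right, and the number 3 libraries lie low except that of cat2 gox2 after high light.

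The mutated genes were read first, as a check of the lines for GOX1 and GOX2. No library came from plants with an intact CAT2, so the CAT2 mutation could not be checked in this way. GOX1 (AT3G14420) had 261 ± 22.7 CPM (SD, n = 3) in cat2 gox1 and 2062 ± 131 CPM in cat2 gox2 under high CO2, and 156 ± 31.5 against 991 ± 49.9 CPM after high light. Its level in cat2 gox1 was thus 12.7% and 15.7% of that in cat2 gox2, and it was higher in cat2 gox2 by a log2 of 2.98 (SE 0.163, adjusted p = 2.16e-05) under high CO2 and 2.67 (SE 0.161, adjusted p = 1.24e-05) after high light. GOX2 (AT3G14415) had 1103 ± 149 CPM in cat2 gox1 and 16.7 ± 0.203 CPM in cat2 gox2 under high CO2, which is 1.51%. After high light it had 558 ± 102 CPM in cat2 gox1, while the cat2 gox2 libraries of numbers 1, 2 and 3 had 7.48, 122 and 6.98 CPM. CAT2 (AT4G35090), mutated in both lines, had 96.3 ± 0.286 and 110 ± 9.25 CPM under high CO2 and 55.6 ± 6.82 and 45.4 ± 1.18 CPM after high light, in cat2 gox1 and cat2 gox2. The difference of CAT2 between the lines did not pass the threshold (log2 0.19, adjusted p = 1; log2 -0.29, adjusted p = 0.154).

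For GOX2 the test depended on the high light library of number 2 of cat2 gox2. The log2 difference between the lines was -6.05 (SE 1.02) under high CO2 and did not pass in the fit of all libraries (adjusted p = 0.307). It passed without that library (-6.05, adjusted p = 4.31e-07), with only the high CO2 libraries fitted (-6.03, adjusted p = 0.000233) and with DESeq2 (-6.03, adjusted p = 2.63e-08). After high light the GOX2 difference was -3.62 (SE 0.909, adjusted p = 0.037), and -6.27 without that library. Leaving out single libraries kept this call in 3 of 12 fits, and the highest adjusted p was 0.0836, without cat2 gox1 high light replicate 1.

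GOX1 and GOX2 are neighbours on chromosome 3. In TAIR10.1, GOX2 spans 4818251 to 4821013 and GOX1 4821391 to 4824178, both on the plus strand, with 12 exons each in the longest transcript and 377 bases between them. Their coding sequences are 92.4% identical over 1104 aligned bases. Of the 50-base words of a GOX1 transcript, 1.19% also occur in GOX2. CAT2 lies on chromosome 4 at 16700312 to 16703504 on the minus strand and has 7 exons. The counts cover whole genes, so no exon was measured separately.

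**Figure D2:**
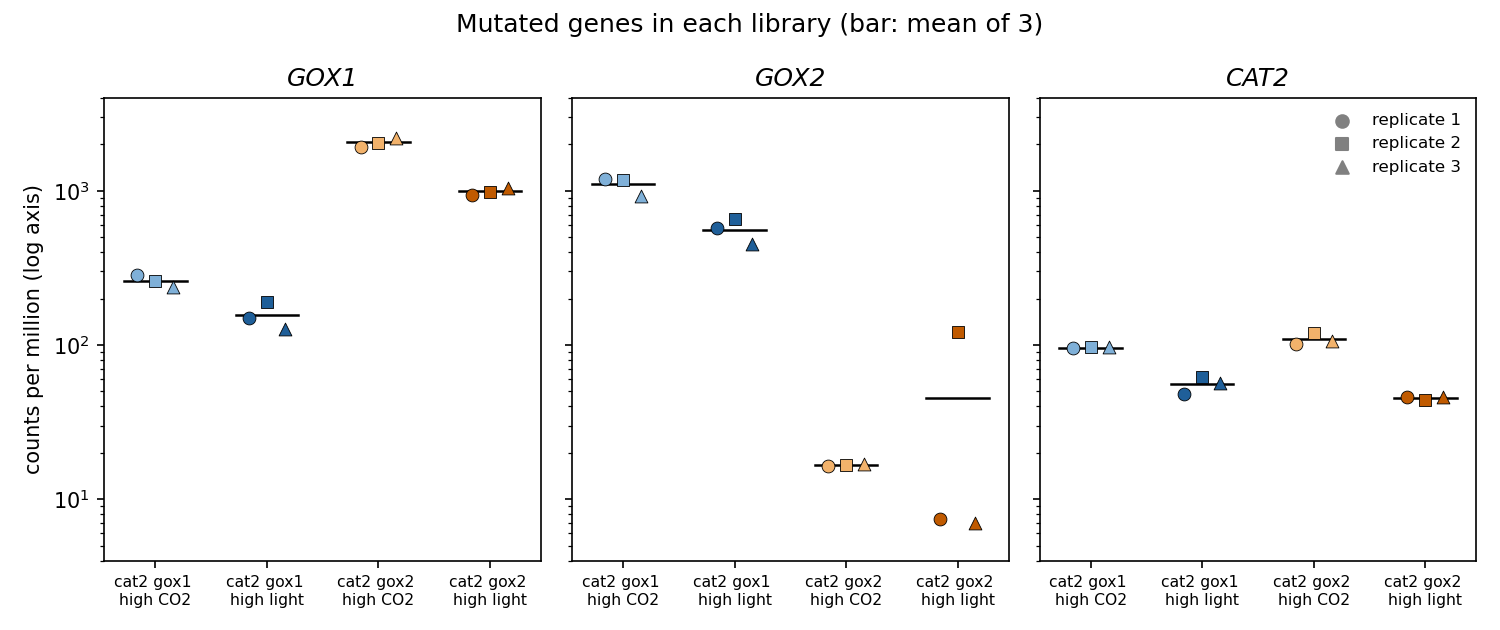
CPM (log axis) of GOX1, GOX2 and CAT2 in each of the 12 libraries. Points are libraries, shaped by replicate, and bars are means of 3. GOX1 is lowest in cat2 gox1, GOX2 is lowest in cat2 gox2, and the number 2 library of cat2 gox2 after high light has 122 CPM of GOX2 against 7.48 and 6.98 in the others of its group.

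High light changed heat shock genes, hydrogen peroxide markers, photorespiratory genes and much of the rest of the leaf transcriptome in cat2 gox1. UGT74E2, a glucosyltransferase gene induced by hydrogen peroxide, rose from 0.565 ± 0.133 to 886.5 ± 324.5 CPM (SD, n = 3; log2 10.59, SE 0.553, adjusted p = 1.7e-07). LHY, a morning-phased transcription factor of the circadian clock, fell from 70.7 ± 16.1 to 3.29 ± 0.588 CPM (log2 -4.42, SE 0.222, adjusted p = 1.57e-07). All 20 tested hydrogen peroxide and mitochondrial stress markers rose, and 23 of 32 photorespiration genes fell. In all, 9880 of 18967 genes passed the threshold, 4858 higher and 5022 lower, and 2779 and 2179 of these changed at least 2-fold.

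Among the other large rises, SUC7, a sucrose transporter gene without a count under high CO2, was at least 980-fold higher. AT1G71000 rose 4204-fold (95% interval 754 to 166100) and UGT73B4, another glucosyltransferase gene, 2184-fold (604 to 18040), both from 1 to 3 counts. HSP23.6-MITO, which encodes a mitochondrial small heat shock protein, rose 1378-fold (381 to 11390). The cytochrome P450 gene CYP81D11 rose by a log2 of 10.08 (SE 0.764), the tau glutathione transferase gene GSTU25 by 9.96 (SE 0.565) and the small heat shock gene HSP23.5 by 9.85 (SE 0.525). The largest falls among genes with a mean of at least 5 CPM and no overlap between the groups were, after AT1G13650 (log2 -4.80, SE 0.8) and AT2G27420 (-4.65, SE 0.378), in LHY, AT5G02760 (-4.10, SE 0.724) and MAKR6 (-3.64, SE 0.403).

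In cat2 gox2 small heat shock genes were among the largest rises. HSP17.6A rose from 0.0853 ± 0.0627 to 479 ± 142 CPM (SD, n = 3; log2 12.38, SE 0.477, adjusted p = 1.4e-08). HSP23.6-MITO rose by a log2 of 12 (SE 0.504), HSP17.6C by 11.78 (SE 0.665) and HSP17.4 by 11.65 (SE 0.733), from 4, 8 and 8 counts under high CO2. AT1G07160, AT1G26410 and AT4G28460 had no count under high CO2 and were at least 1838-fold, 431-fold and 345-fold higher, and AT1G71520 rose 5376-fold (95% interval 965 to 212400). The largest falls, again among genes with a mean of at least 5 CPM and no overlap between the groups, were in LHY (log2 -4.04, SE 0.218), AT5G02760 (-3.61, SE 0.702) and, after PAP14, AT1G13650 (-3.31, SE 0.723). PAP14, a purple acid phosphatase gene, fell by 3.57 on the log2 scale, and its call was lost without cat2 gox2 high light replicates 2 (-3.25, adjusted p = 0.0508) and 3 (-3.46, adjusted p = 0.053). In all, 10793 genes passed the threshold, 5260 higher and 5533 lower, and 3192 and 2450 of these changed at least 2-fold.

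The responses of the lines overlapped widely. In both lines 4235 genes rose, where independent sets would share 1347, and 4318 fell, where they would share 1465. Only 13 genes passed in opposite directions, and 1314 and 2227 passed in cat2 gox1 or cat2 gox2 alone, which by itself does not show a difference between the lines. Across genes the log2 changes of the lines, from separate libraries, correlated with Pearson's r = 0.932 and Spearman's rho = 0.919. Genes are not independent replicates, so no p-value is given for this.

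Among the lists, those of stress defence rose in both lines. The hydrogen peroxide and mitochondrial stress markers had a median log2 change of 4.37 in cat2 gox1 (4.43 with members of few counts at their bound) and 5.04 in cat2 gox2, with 20 of 20 members higher in each, also adjusted over the list alone. AOX1D, an alternative oxidase gene of this list, rose by a log2 of 10 (SE 0.85) in cat2 gox2. Of 25 heat shock and chaperone genes, 20 rose in cat2 gox1 and 24 in cat2 gox2, with the same counts adjusted over the list alone. Their medians were 3.31 and 6.42 (3.31 and 6.29 with members of few counts at their bound). CLPB3, which encodes a chloroplast chaperone, fell in both (log2 -1.16, SE 0.167; -0.77, SE 0.165). Camera called both lists in each line, and the calls held with an estimated correlation (adjusted p = 0.0483 and 0.0482 for the stress markers, 0.031 and 0.0113 for heat shock, in cat2 gox1 and cat2 gox2). Under high CO2 the stress markers already lay higher in the number 3 libraries, by a median log2 of 0.849 in cat2 gox1 and 1.02 in cat2 gox2.

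By camera with its preset correlation, the photorespiration, antenna and Calvin cycle lists were lower in both lines. The call held with an estimated correlation for photorespiration (adjusted p = 0.0364 and 0.047 in cat2 gox1 and cat2 gox2), but not for the antenna (0.482 and 0.519) or the Calvin cycle (0.482 and 0.485). In the photorespiration list 23 of 32 members fell and 3 rose in each line (24 and 23 lower adjusted over the list alone), with medians of -0.817 and -0.811. GLDP2, which encodes a P-protein of glycine decarboxylase, fell, with a log2 of -1.59 (SE 0.165) and -1.55 (SE 0.165), while the catalase gene CAT1 rose by 0.87 (SE 0.129) in cat2 gox1 and the catalase gene CAT3 (AT1G20620) by 0.64 (SE 0.157) in cat2 gox2. GOX1 itself fell in both lines (-0.74, SE 0.152; -1.06, SE 0.153), as did CAT2 (-0.79, SE 0.110; -1.27, SE 0.111). GOX2 had -0.98 (adjusted p = 0.335; 0.000597 without cat2 gox2 high light replicate 2) in cat2 gox1 and 1.44 (adjusted p = 0.167) in cat2 gox2, the latter being -1.21 (adjusted p = 0.000454) without that library. Of 20 antenna genes 18 and 19 fell (19 and 19 adjusted over the list alone), with a median of -1.06 in each line, for example LHCB2.3 (-1.90, SE 0.319; -1.44, SE 0.315). Of 19 Calvin cycle genes 16 and 19 fell (18 and 19 over the list alone; medians -1.27 and -1.25), among them FBA1, a chloroplast aldolase gene (-2.01, SE 0.165; -1.75, SE 0.163). In the number 3 libraries under high CO2 the Calvin cycle list lay lower, at -0.445 in cat2 gox1 and -0.443 in cat2 gox2, and the antenna list at -0.393 and -0.309. After high light these lists lay at -0.452 and -0.79 in number 3 of cat2 gox1, and at -0.0624 and -0.0482 in that of cat2 gox2.

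By camera with its preset correlation, the ethylene, abscisic acid and salicylate lists were higher in both lines, and jasmonate in cat2 gox1. None of these calls held with an estimated correlation (adjusted p = 0.126 and 0.123 for ethylene, 0.515 and 0.578 for abscisic acid, 0.578 and 0.596 for salicylate in cat2 gox1 and cat2 gox2, and 0.482 for jasmonate in cat2 gox1). Of 18 ethylene genes 14 rose and 2 fell in cat2 gox1, and 15 and 2 in cat2 gox2, with the same counts over the list alone and medians of 2.62 (2.38 with 1 member at its bound) and 2.47. ERF6 rose by a log2 of 5.58 (SE 0.313) and 6.02 (SE 0.312), and ACS8, an ACC synthase gene, fell, with a log2 of -3.42 (SE 0.482) and -4.11 (SE 0.504). Of 18 abscisic acid and dehydration genes 14 and 13 rose (14 and 14 over the list alone; medians 1.62 and 1.59), with HAI1, a protein phosphatase gene, at 4.93 (SE 0.629) and 4.39 (SE 0.600). Of 20 salicylate genes 13 and 16 rose (14 and 17 over the list alone; medians 1.13 and 1.42). The cat2 gox1 median was 1.89 without high CO2 replicate 3 of cat2 gox1. Of 25 jasmonate genes 21 rose in cat2 gox1 and 10 in cat2 gox2, with the same counts over the list alone and medians of 2.16 and 0.678. In cat2 gox2 camera did not call this list (adjusted p = 0.0706; 0.721 with an estimated correlation), while fry did (adjusted p = 0.0249). AOC3, an allene oxide cyclase gene of jasmonate synthesis, rose by 3.98 (SE 0.563) and 3.92 (SE 0.559). In the number 3 libraries under high CO2 the jasmonate list lay higher by 0.774 and 1.03 and the abscisic acid list by 0.920 and 0.797. The salicylate list lay higher there by 1.47 and 0.433, and the ethylene list by 0.593 and 0.353.

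By camera with its preset correlation, the indolic glucosinolate and camalexin list was higher, and the aliphatic glucosinolate and flavonoid lists lower, in both lines. None of these calls held with an estimated correlation (adjusted p = 0.196 and 0.459 for indolic, 0.482 and 0.485 for aliphatic glucosinolates, and 0.578 and 0.596 for flavonoids). Of 10 indolic glucosinolate and camalexin genes 7 and 6 rose and 2 fell in each line, with the same counts over the list alone and medians of 4.40 and 4.87. PAD3, which encodes the enzyme of the last step of camalexin synthesis, rose by 6.83 (SE 0.909) and 8.53 (SE 0.987), while MYB34, a regulator of indolic glucosinolates, fell, with a log2 of -1.20 (SE 0.155) and -1.61 (SE 0.158). The indolic call in cat2 gox2 ended under the stricter filter on low counts (4.40, adjusted p = 0.116). Of 13 aliphatic glucosinolate genes 11 and 13 fell (12 and 13 over the list alone; medians -1.15 and -1.58), with their regulator MYB28 at -1.93 (SE 0.251) and -2.09 (SE 0.253). Of 20 flavonoid and anthocyanin genes 7 and 11 fell (7 and 7 over the list alone; medians -1.29 and -1.51), among them the flavonol synthase gene FLS1 (-2.60, SE 0.229; -2.54, SE 0.227). The flavonoid call in cat2 gox1 was lost without cat2 gox1 high CO2 replicate 3 (-0.829, adjusted p = 0.0528). The flavonoid list lay higher in every number 3 library than in the others of its group, by 1.15 and 0.954 under high CO2 and 1.25 and 1.34 after high light, in cat2 gox1 and cat2 gox2.

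By camera with its preset correlation, the senescence and unfolded protein response lists were higher in both lines. Neither call held with an estimated correlation (adjusted p = 0.482 and 0.485 for both lists). Of 12 senescence and chlorophyll breakdown genes 6 and 5 rose, with the same counts over the list alone and medians of 0.889 and 0.801, and SAG21 rose by 5.15 (SE 0.286) and 6 (SE 0.298). The cat2 gox1 median was 1.42 without cat2 gox1 high CO2 replicate 3. In the number 3 libraries under high CO2 this list lay higher by 0.682 and 0.598. Of 16 genes of the unfolded protein response of the endoplasmic reticulum 11 and 12 rose (13 and 13 over the list alone; medians 0.659 and 1.11), with the transcription factor gene BZIP60 at 3.00 (SE 0.241) and 3.98 (SE 0.251).

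The antioxidant, clock, high-light and UV, and sugar starvation lists were not called by camera in either line. Fry passed for all 4 in both lines (adjusted p = 0.00111 and 0.000291, 0.00107 and 0.000148, 0.0106 and 0.00137, 0.0106 and 0.0383, in that order). Of 24 antioxidant genes 9 rose in each line and 6 and 4 fell (9 higher in each, 7 and 5 lower over the list alone; camera adjusted p = 0.169 and 0.213). DHAR2, a dehydroascorbate reductase gene, rose by 3.33 (SE 0.198) and 3.71 (SE 0.202), and VTC2, of ascorbate synthesis, fell, with a log2 of -2.21 (SE 0.218) and -1.71 (SE 0.214). In cat2 gox2 the median of this list was -0.0240 and its mean 0.517. Of 12 clock genes 6 rose in each line and 5 and 4 fell, with the same counts over the list alone (camera adjusted p = 0.115 and 0.0645). PRR5 rose by 4.88 (SE 0.313) and 4.35 (SE 0.303). Of 12 high-light and UV markers 2 and 3 rose and 5 and 6 fell (2 and 4 higher, 5 and 7 lower over the list alone; adjusted p = 0.184 and 0.0925), and of 13 sugar starvation genes 4 and 3 rose and 1 and 2 fell, with the same counts over the list alone (adjusted p = 0.389 and 0.693).

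The lists of guard cells, phloem and dividing cells were called neither by camera nor by fry (fry adjusted p = 0.107 and 0.118, 0.256 and 0.329, 0.229 and 0.118). Of 9 guard cell genes 1 rose and 2 fell in each line, with the same counts over the list alone (adjusted p = 0.389 and 0.434). Of 10 phloem genes 1 rose in each and 4 and 1 fell (1 higher in each, 5 and 1 lower over the list alone; adjusted p = 0.459 and 0.53). Of 8 genes of dividing cells 1 and 2 fell, and 0 and 0 over the list alone (adjusted p = 0.389 and 0.288). The genes of dividing cells lay lower in every number 3 library than in the others of its group, at -0.722 and -0.692 under high CO2 and -0.668 and -0.396 after high light. KNAT6, the tested gene of the shoot meristem list, had 0.636 CPM under high CO2 and 0.132 CPM after high light in cat2 gox1.

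**Figure D3:**
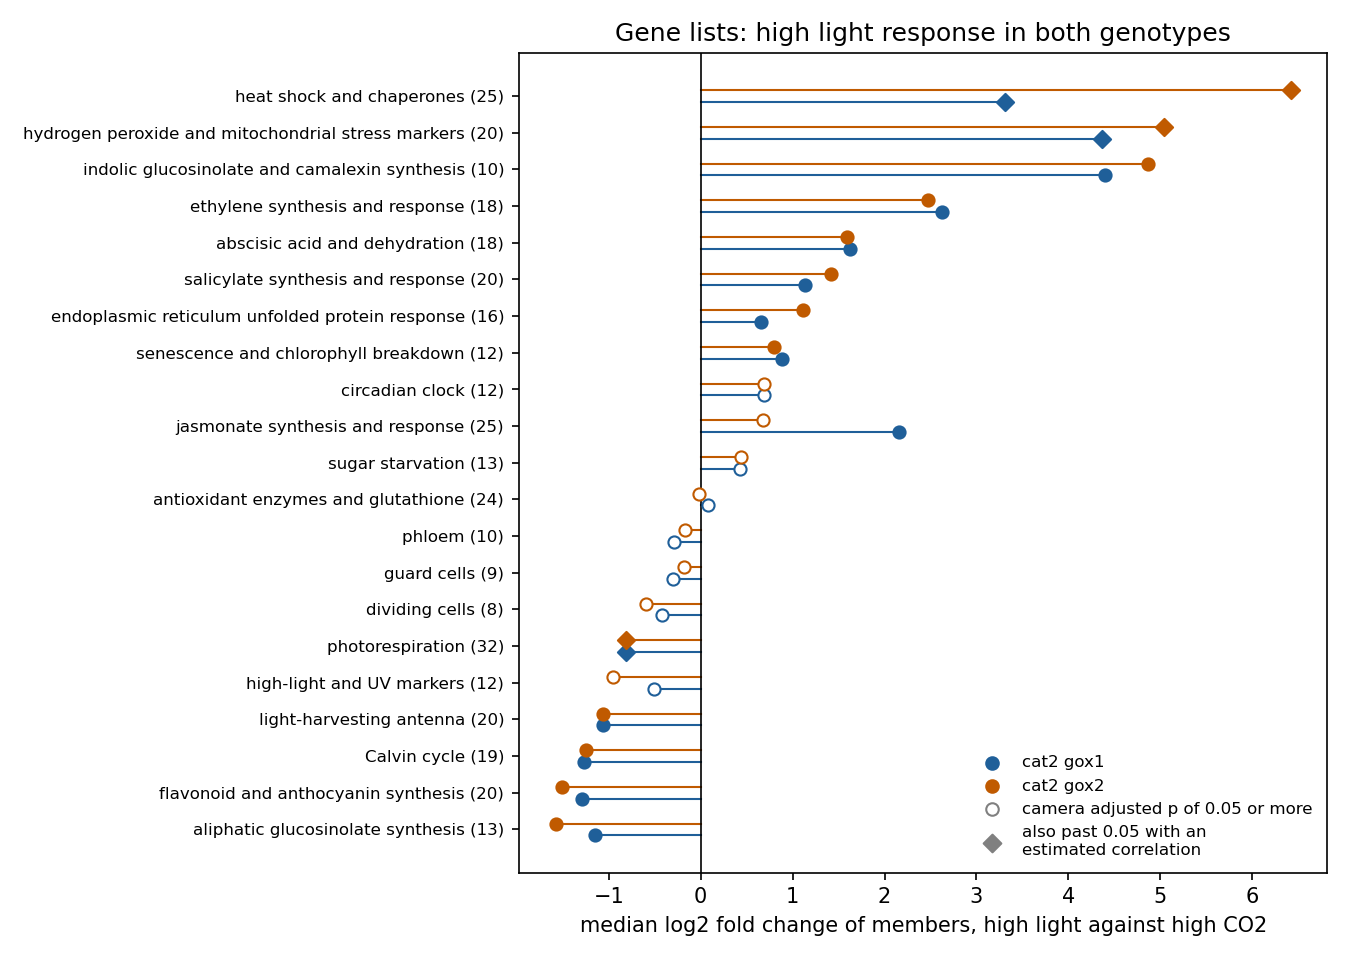
Median log2 fold change, high light against high CO2, of the members of the 21 tested gene lists in cat2 gox1 and cat2 gox2, with the number of tested members in brackets. Filled symbols mark lists past an adjusted p of 0.05 by camera, and diamonds those that also passed with an estimated correlation. Heat shock genes have medians of 3.31 and 6.42, and photorespiration genes of -0.817 and -0.811.

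Under high CO2 the lines differed at few genes, with GOX1 the one with the most counts among them. The other genes that passed both lie on chromosome 3 and were higher in cat2 gox2. AT3G60170 had no count in cat2 gox1 and 2.56 ± 0.430 CPM (SD, n = 3) in cat2 gox2, at least 56.5-fold higher (adjusted p = 0.00459). AT3G29644 had 0.830 ± 0.184 and 3.79 ± 0.358 CPM (log2 2.17, SE 0.247, adjusted p = 0.0149). These 2 genes have too few counts for the rule on named genes and were named after their values were seen. With GOX1 they make 3 genes past the threshold, 3 higher and 0 lower in cat2 gox2, where 511 genes had an unadjusted p under 0.05. DESeq2 called 5 genes, and the fit of the high CO2 libraries alone called 2, GOX1 and GOX2. Because deviations of same-numbered libraries correlated in this comparison, most for number 3, the replicate number was also added as a term, and the same 3 genes passed.

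Over all genes, no list had a member that passed in this comparison except GOX1 in photorespiration. Adjusted over the list alone, 1 photorespiration gene was higher (GOX1) and 1 lower (GOX2) in cat2 gox2. In the same way 2 stress markers and 1 indolic glucosinolate and camalexin gene were higher in cat2 gox2. Camera with its preset correlation called 7 lists, 6 higher and 1 lower in cat2 gox2, and 11 with the replicate term. With an estimated correlation 0 lists passed, and 0 by fry, against 7 by camera with its preset correlation. The medians of the called lists were 0.41 for jasmonate, 0.212 for the stress markers, 0.163 for the antenna, 0.151 for aliphatic glucosinolates, 0.0864 for antioxidants, 0.0691 for photorespiration and -0.199 for the unfolded protein response. The adjusted p with an estimated correlation was 0.102 for photorespiration, 0.572 for antioxidants and 0.871 for the other 5. The mean of the photorespiration list was -0.0294, of opposite sign to its median. This list holds the mutated genes GOX1 and GOX2, so its call can rest partly on the mutations themselves. It was not tested without these genes. In the fit without cat2 gox2 high light replicate 2, which lost that call, GOX2 passed as lower in cat2 gox2. Without cat2 gox2 high CO2 replicate 3 the calls of jasmonate (-0.0332, adjusted p = 0.828), stress markers (-0.124, 0.828), antioxidants (0.0947, 0.135) and aliphatic glucosinolates (0.0427, 0.51) were lost, and without cat2 gox2 high CO2 replicate 2 those of the antenna (0.0355, 0.355), aliphatic glucosinolates (0.0933, 0.226) and the unfolded protein response (-0.197, 0.188). Without cat2 gox1 high CO2 replicate 3 the antenna (0.0789, 0.3), antioxidants (0.0952, 0.138) and the unfolded protein response (-0.0124, 0.792) lost theirs. Without cat2 gox1 high CO2 replicates 1 and 2 the stress markers (0.0269, 0.128; -0.00213, 0.0836) and aliphatic glucosinolates (0.153, 0.0725; 0.131, 0.491) did so, without cat2 gox2 high light replicate 2 photorespiration (0.0696, 0.52) and aliphatic glucosinolates (0.151, 0.0547), and without cat2 gox1 high light replicate 3 aliphatic glucosinolates (0.151, 0.0547). In the jasmonate list, VSP2 had 38 ± 20.7 CPM in cat2 gox1 and 303 ± 448 CPM in cat2 gox2.

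After high light, cat2 gox2 had higher levels of heat shock and chaperone transcripts than cat2 gox1. Hsp70b, which encodes a heat-inducible HSP70 chaperone, had 405 ± 245 CPM (SD, n = 3) in cat2 gox2 and 14.2 ± 2.25 CPM in cat2 gox1 (log2 4.83, SE 0.422, adjusted p = 8.87e-05). HSP17.6A had 479 ± 142 against 26.4 ± 6.52 CPM (log2 4.18, SE 0.296, adjusted p = 2.25e-05). Of 25 heat shock and chaperone genes 21 were higher in cat2 gox2 and 0 lower, and 25 were higher adjusted over the list alone, with a median log2 difference of 2.19. Camera called the list, and the call held with an estimated correlation (adjusted p = 0.00255) and by fry (adjusted p = 5.27e-05).

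Over all genes, 1243 differed between the lines, 1000 higher and 243 lower in cat2 gox2, of which 461 and 38 by at least 2-fold. Apart from heat shock genes, the largest excesses in cat2 gox2 among genes with a mean of at least 5 CPM and no overlap between the groups were in AT1G03070 (log2 5.64, SE 0.502, adjusted p = 9.42e-05) and AT1G22810 (4.43, SE 0.369). HSP17.4 (4.34, SE 0.479), HSP17.6C (4.26, SE 0.432) and HSP70T-2 (3.99, SE 0.358) were also higher. Lower in cat2 gox2 than in cat2 gox1 after high light were, besides GOX2, AT1G22470 (-2.22, SE 0.302, adjusted p = 0.00132), the terpene synthase gene TPS03 (-1.59, SE 0.409, adjusted p = 0.0414), AT3G04000 (-1.34, SE 0.224), ATBRXL2 (-1.25, SE 0.220) and AT4G16870 (-1.20, SE 0.196). TPS03 kept its call in 5 of the 12 fits that left out a library, with a highest adjusted p of 0.159 (without cat2 gox1 high light replicate 3). The count fell to 721 and 757 without cat2 gox1 high light replicates 3 and 1, and to 727 and 776 without cat2 gox2 high light replicates 3 and 2.

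Other lists differed less clearly between the lines after high light. Of 20 hydrogen peroxide and mitochondrial stress markers 8 were higher in cat2 gox2 (12 over the list alone; median 0.909), for example the zinc finger gene ZAT7 (2.22, SE 0.344) and GSTU25 (1.95, SE 0.318). Fry passed for this list (adjusted p = 0.036), and camera with an estimated correlation did not (adjusted p = 0.506). Of 18 ethylene genes 3 were higher (4 over the list alone; median 0.308), with ACS7 at 4.21 (SE 0.472); camera called the list (adjusted p = 0.00251; 0.944 with an estimated correlation, 0.0695 under the stricter filter on low counts). The jasmonate list was called as lower in cat2 gox2 (median -0.386, adjusted p = 0.00654; 0.973 with an estimated correlation) with no member past the threshold, 0 of 25 over the list alone. That call was lost without cat2 gox2 high light replicate 2 (-0.287, adjusted p = 0.0807). The antioxidant list was not called, but APR1 and APR3, genes of sulfate reduction, were higher (1.01, SE 0.168; 0.94, SE 0.183). The clock gene RVE1 had 7.13 ± 1.78 CPM in cat2 gox2 and 0.685 ± 0.0730 CPM in cat2 gox1 (log2 3.37, adjusted p = 2.25e-05). In the unfolded protein response ATERDJ3A, a J-domain protein gene, was higher (2.1, SE 0.261), and that list was not called (adjusted p = 0.196).

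The light response itself was larger in cat2 gox2 for heat shock genes. Hsp70b rose by a log2 of 1.35 (SE 0.383) in cat2 gox1 and 6.42 (SE 0.460) in cat2 gox2, a difference of 5.07 (SE 0.558, adjusted p = 0.00162). HSP101, a disaggregase gene, rose by 4.53 (SE 0.204) and 7.19 (SE 0.230), and 9 of 25 heat shock genes had a larger response in cat2 gox2 (20 over the list alone; median 2.15, or 2.16 with members of few counts at their bound). Camera called the list, also with an estimated correlation (adjusted p = 0.00546), as did fry (adjusted p = 0.00186). HSP101 was chosen from this list after its values were seen. Over all genes 197 had different responses, 189 more positive and 8 more negative in cat2 gox2. Of the 189, 140 rose in both lines and 33 were called as rising in cat2 gox2 alone.

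Camera also called other lists for the difference in response, and none of these held with an estimated correlation (adjusted p = 0.835 for each). The stress markers had a median difference of 0.519 (adjusted p = 0.00277), with 1 of 20 members larger in cat2 gox2 (4 over the list alone). Their call was lost without cat2 gox1 high CO2 replicate 3 (0.0312, adjusted p = 0.308) and cat2 gox2 high CO2 replicate 2 (0.283, adjusted p = 0.0726), and without cat2 gox2 high CO2 replicate 3 the median was 1.1. The unfolded protein response had 0.424 (adjusted p = 0.00383), with ATERDJ3A past the threshold (2.68, SE 0.396), 1 of 16 members also over the list alone. Its call was lost without cat2 gox1 high CO2 replicate 3 (0.17, adjusted p = 0.107) and cat2 gox1 high light replicate 2 (0.264, adjusted p = 0.167), and without cat2 gox2 high CO2 replicate 2 it was 0.261. The jasmonate list had -0.735 (adjusted p = 9.5e-09; -0.242 without cat2 gox2 high CO2 replicate 3) and aliphatic glucosinolates -0.447 (adjusted p = 0.00563), with 0 members past the threshold in each, also over the list alone. The aliphatic call was lost without cat2 gox1 high light replicate 1 (-0.114, adjusted p = 0.339) and cat2 gox2 high light replicate 3 (-0.382, adjusted p = 0.0525), and the median was -0.746 without cat2 gox1 high light replicate 2 and -0.681 without cat2 gox2 high light replicate 1.

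The clock gene RVE1 fell in cat2 gox1 from 6.10 ± 1.11 to 0.685 ± 0.0730 CPM (SD, n = 3; log2 -3.14, SE 0.236), while in cat2 gox2 it had 5.51 ± 0.604 and 7.13 ± 1.78 CPM, a difference of 3.51 (SE 0.308, adjusted p = 0.000809). EGY3, which encodes a chloroplast protein related to metalloproteases, responded more in cat2 gox2 by 4.24 (SE 0.417), HSP70T-2 by 4.13 (SE 0.526), SDR5 by 3.78 (SE 0.476) and AT5G42830 by 3.58 (SE 0.299). IQD22 (-1.39, SE 0.202) and the metal transporter gene NRAMP3 (-1.16, SE 0.160) had more negative responses in cat2 gox2 and were called in each of the 12 fits without a library. The 197 genes became 97 and 112 without cat2 gox1 high light replicates 3 and 1, 113 and 88 without cat2 gox2 high light replicates 2 and 3, 101 and 114 without cat2 gox1 high CO2 replicates 1 and 2, and 97 and 90 without cat2 gox2 high CO2 replicates 1 and 2. DESeq2 called 543 genes, of which 195 were among the 197.

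**Figure D4:**
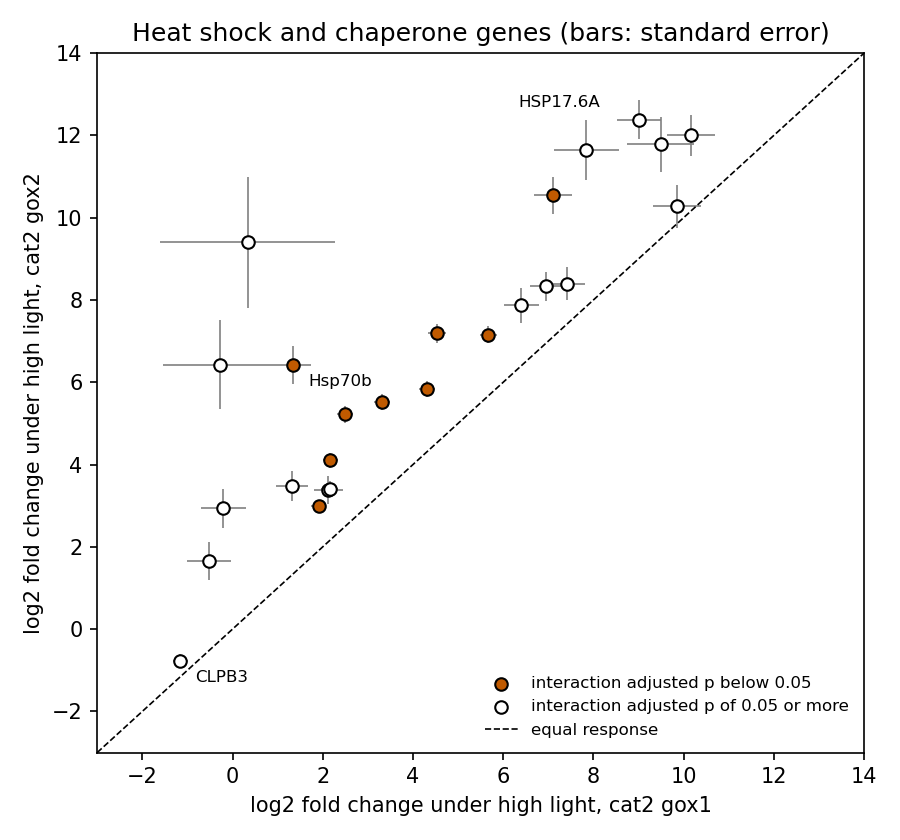
Log2 fold changes of the 25 tested heat shock and chaperone genes under high light, cat2 gox1 on the x axis and cat2 gox2 on the y axis, with standard errors as bars. Filled points passed the test of the difference at an adjusted p below 0.05, and the dashed line marks equal responses. All 25 points lie above the line, with median responses of 3.31 and 6.42.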

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

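This part gives differences between the light responses of the 2 lines and then weighs 3 patterns; the tests of gene length and GC content and of other splits of the libraries were written before their results were seen, while the tests on the GOX2 library, on that library's share in the heat shock difference, on unequal exposure and on the number 3 libraries were chosen after. By the test of the difference itself, 197 genes responded differently in cat2 gox2. Among the named genes these were Hsp70b (5.07), EGY3 (4.24), HSP70T-2 (4.13), SDR5 (3.78), AT5G42830 (3.58), AT1G54050 (3.52), RVE1 (3.51), HSP17.6II (3.44), AT1G59860 (3.41), ATERDJ3A (2.68) and NAC13 (1.15), all more positive in cat2 gox2. More negative were AT3G04000 (-1.88), ATBRXL2 (-1.54), IQD22 (-1.39), NRAMP3 (-1.16), AT3G27870 (-0.97), AT3G03990 (-0.842) and MYB33 (-0.707). Of these 18 genes, 11 kept their call without each library. HSP17.6II kept it in 3 of 12 such fits (highest adjusted p 0.14, without cat2 gox1 high CO2 replicate 2), AT3G04000 in 6 (0.0744, the same library), NAC13 in 4 (0.095, without cat2 gox2 high CO2 replicate 2), ATBRXL2 in 2 (0.125, without cat2 gox2 high CO2 replicate 1) and AT3G27870 in 1 (0.104, without cat2 gox2 high light replicate 3). AT3G03990 and MYB33 kept it in none (0.13 and 0.109, without cat2 gox2 high CO2 replicates 2 and 1).

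By camera with its preset correlation, 5 lists responded differently, with median differences of 2.15 for heat shock and chaperones, 0.519 for the stress markers, 0.424 for the unfolded protein response, -0.735 for jasmonate and -0.447 for aliphatic glucosinolates. The heat shock list alone passed with an estimated correlation, and also by fry. Among 100 drawn splits of the line labels within each condition, 12 gave at least as many genes as the real split, itself included. By the rule written before the counts were seen, a share this large means that chance can account for a count of 197. The sorting of the splits below, by line and by the libraries of number 3, was made after their counts were seen. It limits that reading without reversing it, because most of the 12 splits kept the lines together in high light. The highest of the other splits gave 1943 genes. It kept the lines together in high light, and a count that high points to a structure of the samples. Of the 11 other splits as large, 10 kept the lines together in high light, out of 11 drawn of that kind. Of that kind, splits with both high CO2 libraries of number 3 on one side gave 1943, 1451, 712, 435, 429 and 306 genes. The highest with these libraries apart gave 221. Splits that keep the lines together retain the real difference after high light, so their counts do not show what chance alone gives. The highest with the lines mixed in high light gave 213, above the real count, and every other drawn split of that kind gave 0. Mixed splits move the real difference between the lines into the spread within groups, which lowers their counts.

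The first pattern weighed is the GOX2 count in the number 2 library of cat2 gox2 after high light, at 122 CPM. Reads of GOX1 placed on GOX2, at a share common to these libraries, are argued against by 12.3 GOX2 counts per 100 GOX1 counts, where the other 5 libraries of cat2 gox2 had 0.669 to 0.85. High light material of cat2 gox1 is argued against by a median shift of -3.56% (95% interval -7.72 to 1.25) over 403 genes, where 20.8% would be needed. Libraries 1 and 3 of the group shifted by 5.04% and -1.28% by the same measure. The intervals of these shifts come from resampling genes within 1 library, so they do not cover the spread between libraries. Each library was set against the mean of the other 2 of its group. A positive shift in library 2 by itself therefore lowers the shifts of libraries 1 and 3, which are no independent background. High CO2 material of cat2 gox1 stays open. The shift was 10.2% (8.89 to 11.5) over 358 genes that fall in high light, near the 10.5% needed, against -6.46% and -4.95% in libraries 1 and 3. It was -1.73% (-5.85 to 1.29) over 373 genes that differ between the lines, against 3.73% and -1.05%. The first set was added after the value of the second was seen. Such material would bring each gene to about 10.5% of its level there or more. Of 7234 genes well expressed there, 11 lay below that share in this library, and 17 and 10 in libraries 1 and 3. This goes against such material only weakly, since few genes lay below that share in any library. The high CO2 level is also a mean of libraries that themselves differed. Some pooled plants with an intact GOX2 stay open and were not tested, and no biological explanation was tested.

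The next pattern is the heat shock list, higher in cat2 gox2 after high light by a median of 2.19. A bias by gene length and GC content is argued against as the whole cause, with a median of 2.09 after that trend was removed. The number 2 library alone is argued against too, with 1.78 without it. Unequal exposure of the lines in the light cabinet cannot be told apart from the genotype. The median was higher in 3 of 3 same-numbered pairs (1.97, 2.16 and 2.28), but the light each line received was not measured directly. Exposure that only enlarged all responses alike is argued against, since 10000 matched gene sets had a highest median difference in response of 1.13, against 2.15 for this list. These sets were drawn gene by gene, so their spread holds neither the correlation within the list nor the spread between libraries. Between the lines after high light, the antenna (median 0.146) and Calvin cycle (0.033) lists differed little. The stress markers differed more (0.909), so these lists do not decide. The loss of GOX1 against the loss of GOX2, which the design compares, stays open beside unequal exposure.

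The last pattern is that the high CO2 libraries of number 3 stood apart from numbers 1 and 2 in both lines. Depth is argued against, at 0.928 of the mean of the others in cat2 gox2 and 1.08 in cat2 gox1, while the deviations of the lines correlated at 0.765. A high light response scaled down alike for all genes is argued against in cat2 gox2, with a heat shock median of -0.134 (SE 0.136) where 0.764 would be seen, but stays open in cat2 gox1 (0.286, SE 0.165, against 0.601). Each SE in this paragraph comes from the spread over the genes of a list, with 1 number 3 library per line. It treats genes as independent and leaves out the spread between libraries. A partial light response without heat shock genes also stays open, since the deviations had slopes of 0.182 and 0.119 on the light response over all genes in cat2 gox1 and cat2 gox2, and stress markers (0.849 and 1.02), jasmonate (0.774 and 1.03) and the Calvin cycle (-0.445 and -0.443) lay on the side of high light, while flavonoids (1.15 and 0.954) and aliphatic glucosinolates (0.246 and 0.195) lay against it. Another time of sampling stays open, because the slope of clock genes on their light response was -0.00793 (SE 0.0345) in cat2 gox1 and 0.089 (SE 0.0576) in cat2 gox2, and its rule took the error into account only after a first result, and a lower CO2 level or another shared difference of that repeat was not tested and stays open.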

How the results depend on the processing

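The settings that leave out number 3 libraries were chosen after seeing the data, and the others before. Scaling by the median of ratios and no filter kept all counts within 1.5 times, and the former shifted the median of all genes by at most 0.0571. DESeq2 called 5 genes between the lines under high CO2 and 543 in the interaction, and GOX2 under high CO2 passed with it (-6.03, adjusted p = 2.63e-08). With only the libraries compared, GOX2 was -6.03 (0.000233) under high CO2 and -3.6 (0.0815) after high light, where fewer libraries estimate the spread. Tested against a fold of 1.5, which asks for more than a difference from 0, the counts were 4789 and 5775 for high light in cat2 gox1 and cat2 gox2, 4113 shared, 270 between the lines after high light, 45 in the interaction, and GOX2 was -3.62 (0.128). The stricter filter left 1 gene between the lines under high CO2. With an estimated correlation 3, 3, 0, 1 and 1 lists passed in the 5 comparisons, and by fry 18, 18, 0, 2 and 1, against 14, 13, 7, 4 and 5 by camera with its preset correlation. The replicate block called 11 lists under high CO2. It gave 11102, 11790, 3, 1725 and 285 genes (9815, 10729, 3, 1230 and 189 shared with the fit without it), but same-numbered deviations did not correlate throughout the other comparisons (0.236, 0.0784 and 0.302 for high light in cat2 gox1, -0.138, 0.458 and 0.423 in cat2 gox2, -0.192, 0.0598 and 0.23 between the lines after high light). Without both high CO2 libraries of number 3, 2198 genes differed after high light. Without all libraries of number 3, 1 gene differed under high CO2, the interaction had 38, and GOX2 after high light was -3.2 (0.0981). Without the high CO2 libraries of number 3 and cat2 gox2 high light library 2, GOX2 was -6.15 (1.98e-06) under high CO2, 4 lists passed there, and the light response of GOX2 in cat2 gox2 reversed to -1.12 (0.000525). Leaving out each library in turn gave 8203 to 10739, 9282 to 11467, 2 to 4, 721 to 1624 and 88 to 195 genes, 7366 to 9027 shared, and 13 to 15, 13 to 15, 5 to 10, 3 to 5 and 4 to 8 lists. GOX1 ranged from 2.93 to 3.05 and 2.54 to 2.83, and GOX2 from -6.14 to -5.98 and -6.27 to -3.11. The light response of GOX2 in cat2 gox2 ranged from -1.21 to 1.95 and reversed to -1.21 (0.000454) without cat2 gox2 high light replicate 2, whose GOX2 count was the highest of its group. The test of the unfolded protein response under high CO2 reversed without cat2 gox1 high CO2 replicate 3 (median -0.0124, 0.792; range of the medians -0.268 to -0.0124). Of the results for named genes in these fits, 2203 kept direction and side of the threshold, 146 lost their call and 2 gained one; for lists, 491 kept both and 24 lost their call. Unless stated, the cause was not tested. In simulated counts, changes of 1.5-fold were mostly missed (10% recovered at most), which limits what counts of 0 or few genes can exclude.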

Other observations

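In this part the gene families and the test of chromosome 3 were chosen after the data were seen, while the test of a general enlargement and the splits were written before. A family held the tested genes whose reference symbol or synonyms carry its name, so members without such a name were left out. Of 12 gene families looked at, tau glutathione transferases rose at 16 and fell at 5 of 26 members in cat2 gox1, and rose at 16 and fell at 7 in cat2 gox2 (medians 2.29 and 3.11; adjusted p with an estimated correlation 0.104 and 0.14). UDP glycosyltransferases rose at 30 and 29 of 52 members and fell at 7 and 11 (1.38 and 1.29; 0.104 and 0.202), WRKY factors rose at 26 and 30 of 52 and fell at 5 and 4 (0.806 and 1.03; 0.307 and 0.352), and NAC factors rose at 34 and 35 of 68 and fell at 6 and 7 (0.782 and 0.849; 0.307 and 0.352). Calmodulin-like genes rose at 7 and 8 of 10 and none fell (1.82 and 1.64; 0.104 and 0.0396). SAUR genes fell at 30 of 52 in each line and rose at 8 and 10 (-1.57 and -1.62; 0.343 and 0.448), expansins fell at 11 and 14 of 17 and rose at 1 and 0 (-1.63 and -1.47; 0.307 and 0.352), fasciclin-like arabinogalactan proteins fell at 12 and 11 of 14 (-1.5 and -1.41; 0.307 and 0.352), and aquaporins fell at 11 and 8 of 18 (-0.702 and -0.602; 0.472 and 0.544). Camera with its preset correlation did not call xyloglucan endotransglucosylases (adjusted p = 0.361 and 0.498), cytochromes P450 (0.858 and 0.498) or cyclins (0.103 and 0.25). The calmodulin-like gene CML37, from outside the rule on named genes, rose by a log2 of 5.74 and 8.29, and was higher in cat2 gox2 after high light (2.62, adjusted p = 0.000116).

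A first hypothesis was that the larger heat shock response of cat2 gox2 is part of a general enlargement of its light response. In 10000 sets of genes matched to the list by expression and by their response in cat2 gox1, the median difference was 0.251 (95% of sets from -0.032 to 0.607) and the highest was 1.13, against 2.15 for the list. The slope of the response in cat2 gox2 on that in cat2 gox1 over all genes was 1.06. This argues against a general enlargement as the whole cause. Genes were drawn independently for the sets, whose spread is thus too narrow for a list of correlated genes and leaves out the spread between libraries.

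Another hypothesis was that differences seen in both conditions are line-specific and may lie on chromosome 3, which holds the GOX genes. Distance from the GOX genes along the chromosome was not tested. Of 20 genes that differed the same way in both conditions at an unadjusted p under 0.01 each, 7 lay there (35%), against 19.8% of the others (odds ratio 2.18, 95% interval 0.734 to 5.87, Fisher's exact p = 0.0958), which leaves it undecided. A first version that also held AT3G60170 and AT3G29644, from which the hypothesis came, had 9 of 22 (odds ratio 2.8, Fisher's exact p = 0.0269), and was set aside as circular after its result was seen.

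Splits of the 6 libraries of each comparison were too few for a share under 0.05. For high light the real split gave 9880 genes in cat2 gox1 and 10793 in cat2 gox2, each as 1 of 10 splits, with 0 as the highest other by edgeR's quasi-likelihood test. Between the lines after high light it gave 1243, as 1 of 10, with 0 as the highest other. In these 3 comparisons every other split mixes the groups and moves the real difference into the spread within groups. That lowers their counts, so the 0 does not show what chance alone gives. Under high CO2 the real split gave 3 genes and 2 of 10 splits gave as many; the other, with 273 genes, points to a structure of the samples. The number 3 libraries do not explain it by themselves, since the other 3 splits with both on one side gave 0 genes each by the same test. With the replicate number as a term the real split gave 3 genes.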
